A study of Mus musculus with 8 samples.

How the data were processed

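The series holds single-cell RNA sequencing (10x Genomics 3' v3.1 chemistry) of mouse tail epidermis, taken 28 days after tumour induction in models of basal cell carcinoma and in controls without tumours. The labels name 4 groups of 2 libraries each: Con (no tumour), SmoM2 (an activated form of Smoothened), Gnas-eKO (loss of Gnas, the gene of the stimulatory G protein alpha subunit, in the epidermis) and PKI (an inhibitor peptide of protein kinase A). Per the labels' protocols, epidermis was separated from dermis with trypsin and dispase, strained, and loaded with 1 capture lane per library. Groups were taken from the sample titles. The names of the files that belong to the SmoM2 and Gnas-eKO libraries give the opposite model, so both groups are called by their titles, as the library labelled SmoM2 and the libraries labelled Gnas-eKO.

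The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and barcode. Per the submitters' processing notes they were made with Cell Ranger 7.0.1, STAR 2.7.2a and bcl2fastq 2.20.0 on the mouse build mm10. How doublets or free RNA were treated before deposit is not given in the sources used here. A count matrix was used for 5 libraries: SmoM2 1, Gnas-eKO 1 and 2, and PKI 1 and 2. Count matrices of Con 1, Con 2 and SmoM2 2 were not analysed here, so no comparison with tumour-free epidermis was made. All libraries share 32285 gene features, of which 32158 were matched by gene identifier to a position in GENCODE M21. Counts were not corrected for free RNA, which was measured instead in cells that should lack the genes.

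Barcodes with at least 500 genes and at most 10% mitochondrial counts were kept. Scrublet scores, as scanpy computes them, were taken in each library and the highest removed, at 0.8% per 1000 barcodes, which took out 2420 barcodes (4.25% to 7.49% of a library). The 33692 cells left (5058 to 8584 per library) were normalised to the same total per cell, log transformed, reduced to 2000 variable genes and 30 principal components, joined to 15 neighbours and clustered by the Leiden method at resolution 1, which gave 43 clusters. Each cluster was set against marker lists fixed before the data were examined and took the class with the highest mean standardised marker level, provided that at least 3 of its markers were detected in 10% or more of the cluster's cells at 1.5 times or more the level in the other cells. A cluster stayed unnamed when its 10 leading genes held more markers of another class, or when its median UMI count was under 1/3 of its own libraries' medians and no marker led it. Keratinocytes were all cells of named keratinocyte clusters and of unnamed clusters with keratins among their 100 most abundant genes and at most 1 marker of any non-keratinocyte class among the 30 genes highest by fold. The unnamed clusters also needed a keratinocyte class as their highest-scoring class, or under 3 markers of that class at the level required above. This rule for unnamed clusters was loosened after the clusters were seen, because its first form had left out a cluster rich in Hedgehog targets. It gave 33071 keratinocytes (97.3% to 98.4% of a library). The 12 unnamed keratinocyte clusters held 29.7% to 32.6% of cells in 4 libraries and 45.5% in PKI 2. Keratinocyte clusters of low UMI count held 26.2% of the cells of PKI 2 and 1.55% to 3.36% of the others.

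Raw counts were summed per library over keratinocytes and over each class with at least 20 cells in every library. Cells were never used as replicates. Sums were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in 1 fit of the 5 libraries, with 2 residual degrees of freedom. The comparisons were the libraries labelled Gnas-eKO against PKI, the library labelled SmoM2 against the mean of the other 2 groups, and the library labelled SmoM2 against each of them. The SmoM2 group had 1 library and was assumed to vary like the others. The labels do not say whether libraries of a group came from separate animals. Within the Gnas-eKO and the PKI group the libraries differed in sex, so 1 animal did not give both. The p-values measure the spread between these libraries, which holds this sex difference and may in part be technical. 2 of the 5 libraries came from males and 3 from females by Xist and 4 Y-linked genes. Replicate number 1 was male and number 2 female in both the Gnas-eKO and the PKI group.

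The genes named below follow a rule fixed before the data were examined. For the first 2 comparisons it takes up to 8 genes per direction with the largest change among those past the threshold, with a mean of at least 20 CPM (counts relative to library size) and no overlap between the sides, leaving out mitochondrial, ribosomal protein and predicted genes. It adds up to 3 members of each of the 4 lists with the smallest p in each direction, and 13 genes that are always given, among them Gnas, Smo and Gli1. For each class it takes the 2 largest changes per direction. Genes outside it are said to be chosen after their values were seen, and 1 gene that it names is not reported here. In all, 30 gene lists fixed in advance were tested with camera (preset correlation 0.01, adjusted over the 60 tests), and again with an estimated correlation and with fry. CPM of tested genes are on TMM-scaled library sizes, and CPM of Gnas by class and library on plain totals. Coordinates are mm10, 1-based.

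Alternatives fixed in advance were RLE size factors, DESeq2, no low-count filter, up to 20% mitochondrial counts, at least 1000 genes, no doublet removal, Leiden resolution 0.5 and 2, a replicate block, equal library totals, the 4 Gnas-eKO and PKI libraries only, all cells, and leaving out each Gnas-eKO or PKI library. A sex term, restricted keratinocyte sets, single clusters and class lists were added after seeing the data.

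The test was run first on simulated counts drawn from the real means with 200 genes changed. For the libraries labelled Gnas-eKO against PKI it recovered 48.5% of genes changed by a log2 fold of 1 and 97.0% of those changed by 3, with 5 false calls. For the library labelled SmoM2 against the mean of the others it recovered 48.0% and 89.0%, with 8 false calls. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. Intervals on shares are exact 95% binomial intervals and cover counting error only.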

Results

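Tail epidermis of 3 mouse models of basal cell carcinoma was compared by single-cell RNA sequencing 28 days after tumour induction. The 5 libraries analysed held 6209 to 10491 barcodes and 116466261 to 172258444 UMIs each, with medians of 13984 to 15670 UMIs and 4316 to 4539 genes per barcode. The lists of the 3 libraries not analysed here held 12117 (Con 1), 14026 (Con 2) and 17953 (SmoM2 2) barcodes. The models act on the Hedgehog pathway at Smoothened (SmoM2), at the stimulatory G protein (Gnas-eKO) and at protein kinase A (PKI).

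Gnas (ENSMUSG00000027523, chromosome 2, 174284320 to 174346744), the gene targeted in the Gnas-eKO model, was low in keratinocytes of the library labelled SmoM2 and not in those labelled Gnas-eKO. Its summed keratinocyte level was 93.9 CPM (10875 counts) in the library labelled SmoM2, 362 and 367 CPM in those labelled Gnas-eKO, and 420 and 401 CPM in PKI. The log2 fold change was -2.06 (SE 0.10, adjusted p = 0.0203, edgeR quasi-likelihood test) for the library labelled SmoM2 against the mean of the other groups. For the libraries labelled Gnas-eKO against PKI it was -0.16 (SE 0.08, adjusted p = 0.458). In immune cells, where an epidermal deletion should not act, Gnas stood at 575 CPM in the library labelled SmoM2 and at 551 to 614 CPM in the other 4. The target gene thus goes against the titles and with the file names, and every direction below depends on this conflict. A 3' tag reports a deletion only if the tag or the transcript's stability is affected, and the labels do not say which exon was removed. The adjusted p rose to between 0.113 and 0.146 when any Gnas-eKO or PKI library was left out, and to 0.0548 with a sex term.

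**Figure D1:**
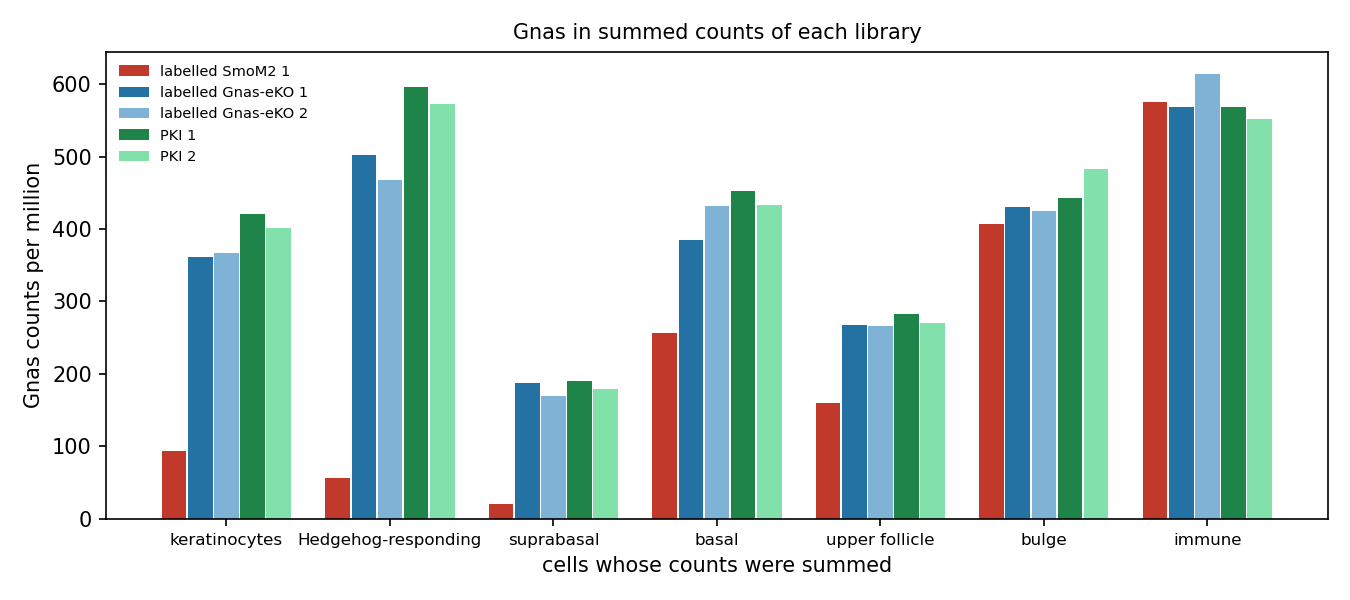
Gnas in CPM (vertical axis, plain library totals) in the summed counts of keratinocytes, 5 keratinocyte classes and immune cells (horizontal axis), 1 bar per library. The library labelled SmoM2 stands at 93.9 in keratinocytes, against 362 to 420 in the others, and at 575 in immune cells, against 551 to 614.

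By keratinocyte class, Gnas in the library labelled SmoM2 was lower by a log2 fold of -3.20 (SE 0.15, adjusted p = 0.00209) in Hedgehog-responding cells and -3.24 (SE 0.16, adjusted p = 0.0209) in suprabasal cells. In basal cells it was -0.82 (adjusted p = 0.373), in upper follicle cells -0.81 (adjusted p = 0.0671), in sebaceous cells -0.80 (adjusted p = 0.862) and in bulge cells, the follicle's stem cell region, -0.15 (adjusted p = 0.976), none of which passed edgeR's test. After thinning every cell to 5000 UMIs, at least 1 Gnas UMI was found in 19.3% of Hedgehog-responding cells of the library labelled SmoM2 (exact 95% interval 17.5% to 21.2%, unthinned 41.1%) and in 85.4% to 92.1% of those of the other 4. The thinned share was 7.74% in its suprabasal cells, 51.6% in upper follicle, 62.8% in basal, 85.5% in bulge and 89.9% in immune cells. No cell type that should lack Gnas was measured, so the level of free Gnas RNA behind these shares is unknown.

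Among Hedgehog targets in the sum of keratinocytes, Gli1 differed little between the groups while Hhip was higher in the libraries labelled Gnas-eKO, past the threshold in Hedgehog-responding cells and not in the sum of keratinocytes. Gli1, a transcription factor induced by the pathway, was at 54.4 CPM in the library labelled SmoM2, 51.6 ± 6.67 (SD, n = 2) in those labelled Gnas-eKO and 49.4 ± 0.183 in PKI. In basal cells alone, on plain totals, it was at 18.2 CPM in the library labelled SmoM2 and at 5.70 to 7.19 in the other 4. Ptch1 was at 75.5 against 38.0 to 48.7 there. Basal cells had 0 genes past edgeR's threshold for this library, against 1033 at an unadjusted p under 0.05 and 63 by DESeq2. Hhip, a pathway antagonist that is itself a target, was at 163 ± 9.95 CPM in the libraries labelled Gnas-eKO against 79.0 ± 13.9 in PKI (log2 1.04, SE 0.14, adjusted p = 0.102, edgeR) and at 79.1 in the library labelled SmoM2. In Hedgehog-responding cells alone Hhip passed in the first of these comparisons (log2 1.17, SE 0.14, adjusted p = 0.0253), as did the Hedgehog coreceptor gene Gas1 (0.90, SE 0.13, adjusted p = 0.0486), which was chosen after its values were seen. Cluster 18 of this class, with Hhip among its 10 leading genes, held 123 and 225 cells of the libraries labelled Gnas-eKO and 40 and 42 of PKI. Within cluster 1, on plain totals, Hhip was at 544 and 424 CPM against 193 and 266. How much of the class difference comes from cluster 18 was not tested. The pathway list as a whole did not pass in Hedgehog-responding cells (median 0.05, adjusted p = 0.260, and p = 0.352 with an estimated correlation), with 5 of 17 members higher and 2 lower adjusted over the list alone. Ptch1, the Hedgehog receptor, was at 739 ± 78.6, 569 ± 18.2 and 789 CPM in the same order (adjusted p = 0.289 and 0.741). Smo was at 165 ± 29.0, 148 ± 15.6 and 142 CPM, and Sox9 at 228 ± 18.8, 224 ± 52.2 and 219 CPM. The Hedgehog pathway list had a camera adjusted p of 0.311 for the libraries labelled Gnas-eKO against PKI and 0.188 for the library labelled SmoM2 (p = 0.428 and 0.329 with an estimated correlation). In these, 3 and 1 of the 18 measured members were higher when adjusted over the list alone. For the first comparison the list's median (0.04) and mean (-0.04) differed in sign.

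Between the libraries labelled Gnas-eKO and PKI, a few genes differed by a large factor. Skint3 and Skint4, members of a family of epidermal immunoglobulin-like genes, gave 1 and 0 counts and 4 and 2 counts in the libraries labelled Gnas-eKO, against 56.0 CPM (5895 and 8582 counts) and 67.4 CPM (6652 and 10983 counts) in PKI and 31.1 and 45.7 CPM in the library labelled SmoM2. Ostf1 fell from 80.2 ± 1.99 to 2.56 ± 0.0457 CPM (n = 2 each; log2 -4.97, SE 0.09, adjusted p = 8.8e-04) and Shroom3, a regulator of apical constriction, from 57.1 ± 1.18 to 25.1 ± 0.832 CPM (log2 -1.18, SE 0.08, adjusted p = 0.0333). Cwc22, a splicing factor (log2 1.72, SE 0.07, adjusted p = 0.00777), the protease gene Prss22 (1.63, SE 0.09, adjusted p = 0.0177) and Glo1, which detoxifies methylglyoxal (1.48, SE 0.10, adjusted p = 0.0333), rose. In all, 20 of 20271 genes passed edgeR's test, 9 higher and 11 lower. Those named here differed the same way in the male and in the female pair, which the naming rule's lack of overlap fixes in advance. At an unadjusted p under 0.05 stood 2750 genes. DESeq2 called 688 and the fit with a replicate block 101, each with these 20 among them. Without Gnas-eKO 1, Gnas-eKO 2, PKI 1 or PKI 2 the count was 5, 8, 6 and 4, with 4 of the 20 kept each time. Skint genes, Cwc22 and Glo1 have related copies in the genome, so their counts are uncertain. In non-keratinocytes, 13 of the 14 called genes whose mean level there was at least 50% of that in keratinocytes differed in the same direction, Vill on 1 to 3 and Pou5f1 on 0 to 4 counts per library.

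The differentiation keratin Krt10 was at 6130 ± 90.7 CPM in the libraries labelled Gnas-eKO and 4453 ± 258 in PKI (log2 0.46, SE 0.11, adjusted p = 0.256), and Krt17 at 3526 ± 243 and 2427 ± 402 (0.54, SE 0.16, adjusted p = 0.285). Krt1 (adjusted p = 0.799), Krt5 (0.515) and Krt14 (0.851) had smaller differences relative to their spread, as did Pkia (0.550) and Prkaca (0.636), an endogenous inhibitor and a catalytic subunit of protein kinase A. Of the 30 gene lists, 3 passed camera's test with the preset correlation and none after adjustment with an estimated one. The tail scale and hair keratins were lower (median log2 -1.49, 9 of 11 members below 0, adjusted p = 5.7e-06), with p = 0.0328 with an estimated correlation. No member passed over all genes by edgeR, against 6 at an unadjusted p under 0.05, 5 lower by DESeq2 and 6 lower when adjusted over the list alone, and Krt31 (-2.04), Krt86 (-1.49) and Krt71 (-1.99) led it. Scale and hair shaft cells made up 0.132% ± 0.000798 (SD, n = 2) of the libraries labelled Gnas-eKO, with 9 cells in each, and 0.382% ± 0.0367 of PKI, with 18 and 35 cells (exact permutation p = 0.333, two-sided, the smallest possible). Granular and cornified envelope genes were higher (median 0.45, 16 of 18 above 0, adjusted p = 7.3e-05), with p = 0.123 with an estimated correlation. Lor (0.91), Hrnr (1.08) and Flg2 (0.91) of this list had adjusted p from 0.218 to 0.256. EdgeR called 0 members over all genes and 0 adjusted over the list alone, against 10 at an unadjusted p under 0.05 and 4 higher by DESeq2. Proliferation genes were higher by a small amount (median 0.20, 24 of 24 above 0, adjusted p = 0.00224), with p = 0.489 with an estimated correlation and 0 members called by edgeR over all genes, adjusted over the list alone or at an unadjusted p under 0.05, and 0 by DESeq2. Beside these lists, clusters of low UMI count, 1 of them led by Krt36 and Krt84, held 26.2% of the cells of PKI 2 and 1.55% to 3.36% of the other libraries.

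Other lists did not pass. The lists next to them by p were glycolysis and hypoxia (adjusted p = 0.0622, Slc16a3, Slc2a1 and Gapdh leading), the ATF4 and amino acid response (0.0742, Slc7a5 at log2 0.72, Psat1 and Slc3a2) and the upper follicle and infundibulum list (0.0842). On the lower side the bulge and germ list (0.442, with Cd34 at -0.72, Alcam at -0.50 and Cdh3 at -0.27), the melanocyte list (0.613) and the mitochondrial transcripts (0.467) had the smallest p after the hair keratins. The cAMP and CREB target list was at an adjusted p of 0.203.

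The library labelled SmoM2 differed from the mean of the others by 17 genes, 12 higher and 5 lower, and 0 of the 18 measured members of the Hedgehog pathway list were among them by edgeR, against 5 at an unadjusted p under 0.05 and 1 by DESeq2. Enpp1, a nucleotide pyrophosphatase, was at 80.5 CPM against 14.8 ± 0.488 and 15.9 ± 3.57 in the libraries labelled Gnas-eKO and PKI (log2 2.39, SE 0.17, adjusted p = 0.0416). Baiap2l1, an actin-bundling adaptor, was at 174 CPM against 55.4 ± 3.17 and 59.8 ± 1.70 (1.60, SE 0.08, adjusted p = 0.0189). Ostf1 was at 1.79 CPM, near the 2.56 ± 0.0457 of the libraries labelled Gnas-eKO and below the 80.2 ± 1.99 of PKI (adjusted p = 0.00739 against the mean of both). The 17 genes are those of 1 library, which was assumed to vary like the other groups. The count fell to 0 without PKI 1 or without PKI 2, to 3 without Gnas-eKO 1 and to 4 without Gnas-eKO 2. DESeq2 called 297 genes, among them these 17.

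Of the lists, 8 passed camera's test for this comparison and none after adjustment with an estimated correlation. The tail scale and hair keratins were higher (median log2 1.56, 7 of 11 above 0, adjusted p = 7.7e-11), with p = 0.0176 with an estimated correlation. Krt31 passed over all genes (3.08, SE 0.17, adjusted p = 0.0321), 6 members did adjusted over the list alone, and Krt71 (2.86) and Krt86 (1.97) followed. Scale and hair shaft cells made up 1.13% of this library and 0.132% to 0.408% of the others. Immune markers were higher in the keratinocyte sums (median 1.03, 10 of 10 above 0, adjusted p = 5.7e-06), with p = 0.0328 with an estimated correlation, at levels under 0.3 CPM for Cd3d, Trdc and Cd3g, while immune cells made up 1.74% of this library against 0.395% to 0.952%. Melanocyte markers were higher (median 0.55, adjusted p = 0.0187), with p = 0.324 with an estimated correlation. Immediate early genes were higher (median 0.36, 16 of 18 above 0, adjusted p = 7.5e-05), with p = 0.270 with an estimated correlation, led by Egr3 (0.59), Jun (0.43) and Ier3 (0.67). Sebaceous lipid synthesis genes were higher (median 0.31, 14 of 16 above 0, adjusted p = 3.1e-04), with p = 0.248 with an estimated correlation, led by Acsbg1 (0.40), Awat1 (0.72) and Plin2 (0.31). Glycolysis and hypoxia genes were higher (median 0.20, 17 of 20 above 0, adjusted p = 0.00224), with p = 0.311 with an estimated correlation. Granular and cornified envelope genes were lower (median -0.44, 14 of 18 below 0, adjusted p = 2.2e-04), with p = 0.131 with an estimated correlation, led by Hrnr (-1.59), Cnfn (-0.65) and Nccrp1 (-0.79). Mitochondrial transcripts were lower (median -0.20, 7 of 8 below 0, adjusted p = 0.0440), with p = 0.419 with an estimated correlation, led by mt-Cytb (-0.41), mt-Atp6 (-0.33) and mt-Nd4 (-0.24). Among single members of these 8 lists adjusted over the list alone, 2 immune, 2 sebaceous and 1 immediate early gene were higher and 2 envelope genes lower. Over all genes edgeR called Krt31 alone among the members of the 8 lists, while DESeq2 called 6 hair keratins, 2 immediate early genes and 1 sebaceous gene higher and 4 envelope genes lower. At an unadjusted p under 0.05 stood 6 hair keratins, 6 envelope, 4 sebaceous, 3 immediate early, 3 immune and 2 glycolysis genes, 1 melanocyte gene and 1 mitochondrial transcript.

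The cAMP and CREB targets, which protein kinase A activates, did not pass in the library labelled SmoM2 (median -0.30, 13 of 17 below 0, adjusted p = 0.144, and p = 0.402 with an estimated correlation), with Sik1 at -0.71, Per1 at -0.66 and Nr4a2 at -0.84. Sik1 was at 57.7 CPM there, 60.0 and 74.0 in PKI and 154 and 113 in the libraries labelled Gnas-eKO. The interfollicular basal list was at an adjusted p of 0.200, with Itgb4 at -0.27, Lama3 at -0.23 and Col17a1 at -0.36. Set against each other group alone, the library labelled SmoM2 differed by 12 genes from those labelled Gnas-eKO (7 higher, 5 lower, 326 by DESeq2) and by 17 from PKI (11 higher, 6 lower, 387 by DESeq2).

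Within cell classes, the Hedgehog-responding cells held the most differences between the libraries labelled Gnas-eKO and PKI. In them 75 genes rose and 61 fell by edgeR, against 256 and 331 by DESeq2, so the balance of directions depends on the test. These libraries filled cluster 18 of the class differently, as given above for Hhip. By the naming rule, which needs a mean of at least 20 CPM, the largest rises were those of the palmitoyltransferase gene Zdhhc14 (log2 3.72, SE 0.16, adjusted p = 0.00172), at 186 and 242 CPM against 16.2 and 16.3, and the histone gene Hist1h2ak (2.08, adjusted p = 0.0156). Skint4 gave 0 counts there in both libraries labelled Gnas-eKO and 59.6 and 47.9 CPM in PKI. Bulge cells held 39 changed genes, against 17 by DESeq2, and 22, 18, 98 and 193 without Gnas-eKO 1, Gnas-eKO 2, PKI 1 and PKI 2. Prss22 (1.95) and the kinase gene Dapk2 (1.92) rose in them and Cd200, a bulge surface marker, fell (-4.72, SE 0.41, adjusted p = 6.5e-05). Upper follicle cells held 33, among them Serpinb3b (1.74), suprabasal cells 21, among them Hebp1 (1.90), and basal cells 8. Without Gnas-eKO 1, Gnas-eKO 2, PKI 1 and PKI 2 these counts were 21, 14, 37 and 65 in upper follicle cells, 5, 7, 14 and 19 in suprabasal cells and 13, 26, 0 and 0 in basal cells. In Hedgehog-responding cells they were 137, 350, 222 and 952. Ostf1 and Cwc22 passed in 5 classes each. Among the largest changes that the rule names, Ostf1 fell in the basal (-4.26), bulge (-4.30) and Hedgehog-responding (-4.85) classes. Cwc22 rose among them in the basal (1.60), suprabasal (1.77) and upper follicle (1.61) classes. In sebaceous cells edgeR called 0 genes, against 759 at an unadjusted p under 0.05 and 49 by DESeq2. Counts per class do not show that an effect differs between classes. The difference between suprabasal and basal cells was tested directly and gave 0 genes by edgeR, 693 at an unadjusted p under 0.05 and 11 by DESeq2.

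In the library labelled SmoM2, Hedgehog-responding cells carried 79 changed genes, 59 higher and 20 lower. Among those with a mean of at least 20 CPM and no overlap with the other libraries, the largest changes were those of the protease inhibitor gene Cstdc5 (3.80, SE 0.24, adjusted p = 0.00466) and Enpp1 (3.46, SE 0.17, adjusted p = 0.00209) upwards and of Gnas and the hypoxia factor Epas1 (-2.06, adjusted p = 0.00466) downwards, with predicted genes left out. Genes of lower level changed more, such as Cabp1 (5.81) and Tslp (4.05), both chosen after their values were seen. Suprabasal cells held 20 changed genes, with Tchh, a structural protein of the hair shaft's inner sheath, at 211 CPM against 5.69 to 14.6, and Skint9 at 135 CPM against 69.9 and 102 in PKI and 0 counts in both libraries labelled Gnas-eKO. Tchh is among the 10 leading genes of the scale and hair shaft cluster, which held 73 cells of this library and 9 to 35 of the others. Free RNA was therefore not told apart from a rise of Tchh within suprabasal cells. Upper follicle cells held 17, with 1 copy of the skin chemokine gene Ccl27a (1.89, adjusted p = 0.00571) and Baiap2l1 (1.34) higher and Rab40b (-1.58) lower. Bulge cells held 7, against 1 by DESeq2 and 5, 2, 50 and 73 without Gnas-eKO 1, Gnas-eKO 2, PKI 1 and PKI 2, with Ubtd2 (1.97) and Enpp1 (1.42) higher and the receptor gene Erbb4 (-3.09) and Gpx2 (-2.55) lower. Basal and sebaceous cells had 0 by edgeR, against 1033 and 668 at an unadjusted p under 0.05 and 63 and 25 by DESeq2. The Hedgehog-responding class was filled differently: cluster 1 held 371 and cluster 3 held 684 of its cells in the library labelled SmoM2, against 440 to 611 and 300 to 563 in the others. Without Gnas-eKO 1, Gnas-eKO 2, PKI 1 and PKI 2 the count was 163, 453, 282 and 505 in Hedgehog-responding cells, 0, 0, 13 and 14 in suprabasal cells and 1, 1, 16 and 23 in upper follicle cells. The class totals, 123 in this comparison and 237 for the libraries labelled Gnas-eKO against PKI, stayed within 1.5 times without Gnas-eKO 1 (172 and 198) and changed by more without Gnas-eKO 2, PKI 1 or PKI 2, to as many as 616 and 1233 without PKI 2.

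The shares of the keratinocyte classes varied between libraries of a group as well as between groups. Hedgehog-responding cells made up 28.8% of the library labelled SmoM2, 25.8% ± 5.93 (SD, n = 2) of those labelled Gnas-eKO and 22.5% ± 6.10 of PKI (exact permutation p = 0.667, two-sided, smallest possible 0.333). Their difference between the libraries labelled Gnas-eKO and PKI, 3.33 points, was 5.36 to 7.47 under the 5 other cell filters and resolutions. These shares are of the named class and leave out unnamed clusters 0 and 2 (2886 and 2361 cells). Over the Gnas-eKO and PKI libraries, Ptch1 averaged 1478 CPM in cluster 0 and 1602 in cluster 2, against 1355 in the class. The class thus does not hold every cell with Hedgehog output. Basal cells made up 9.07%, 14.0% ± 4.70 and 12.3% ± 1.75, and suprabasal cells 9.69%, 11.5% ± 0.839 and 10.4% ± 0.0306. Upper follicle cells made up 9.94%, 10.8% ± 0.783 and 9.28% ± 2.58, sebaceous cells 4.68%, 4.04% ± 0.700 and 4.75% ± 0.637, and bulge cells 1.33%, 1.35% ± 0.0439 and 1.19% ± 0.270. The library labelled SmoM2 was below the other 4 in basal (10.7% to 17.4%) and suprabasal cells (10.4% to 12.1%) and above them in scale and hair shaft cells (1.13% against 0.132% to 0.408%). With 2 libraries per group no share could reach an exact permutation p under 0.333. The unnamed keratinocyte clusters and the low-UMI cells of PKI 2 are part of each denominator and lower the shares of PKI 2, except that of sebaceous cells. Low-UMI cluster 26 was named sebaceous and held 175 of the 369 sebaceous cells of PKI 2, against 30 to 56 cells in each of the others.

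**Figure D2:**
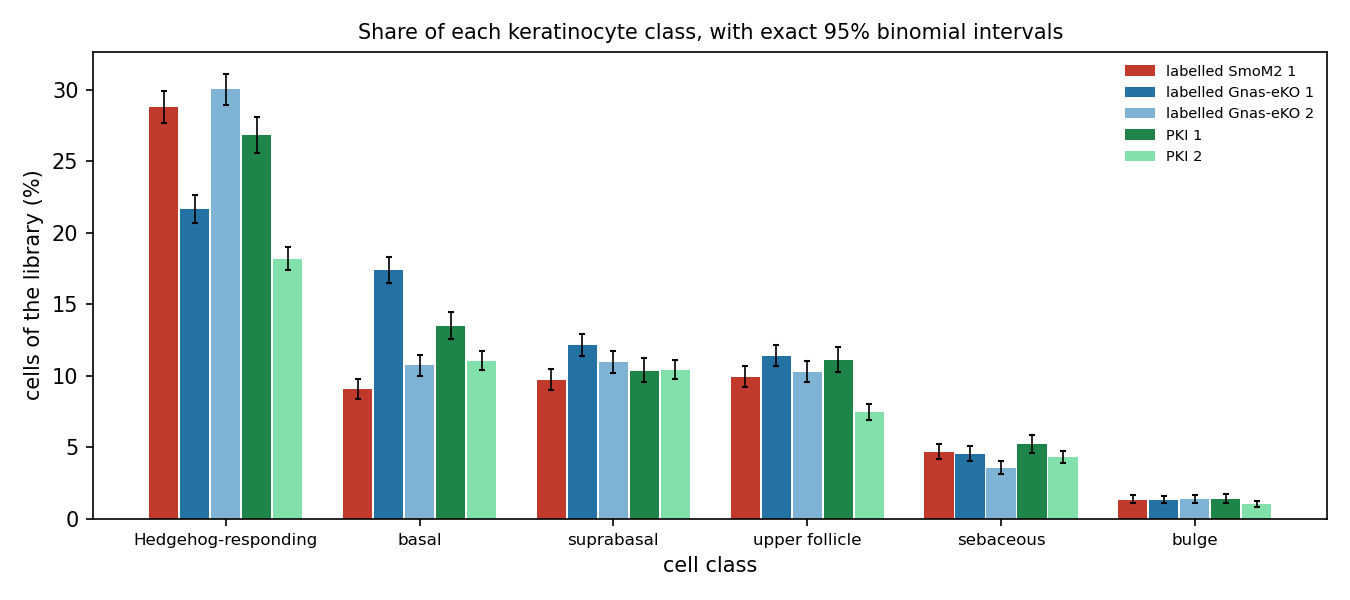
Share of each library's cells (vertical axis, percent) in 6 keratinocyte classes (horizontal axis), 1 bar per library with exact 95% binomial intervals, which cover counting error only. Hedgehog-responding cells stand at 28.8% in the library labelled SmoM2, and at 26.8% and 18.2% in the PKI libraries, which differ from each other by more than the group means do.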

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

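The tests of the exchanged titles, of Hedgehog output on Gnas, of neighbouring genes, of called genes against the free RNA of each library and of risen keratins in single cells were chosen after the results they bear on were seen, as were the interaction tests of Gnas between classes. The other tests were set before their results.

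The fall of Gnas in the library labelled SmoM2 was smaller in upper follicle, basal and bulge cells than in Hedgehog-responding cells, in a test of the difference itself with library as a block. The log2 difference was 2.35 (SE 0.11, adjusted p = 4.1e-04, edgeR) for upper follicle cells, 2.37 (SE 0.13, adjusted p = 0.0107) for basal cells and 3.04 (SE 0.17) for bulge cells. The p of the bulge test is not used, because that fit gave all genes 1 shared variance. For suprabasal cells it was -0.08 (SE 0.14, adjusted p = 0.976). Within the basal class, Gnas in this library was at 389 CPM in cluster 4, against 469 to 533 in the others, and at 45.8 CPM in cluster 7, against 335 to 389, where Gli1 was also higher (16.4 CPM against 1.55 to 2.39).

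Low Gnas in the library labelled SmoM2 was set against an exchange of titles and against an effect of Hedgehog output. What an effect of Hedgehog output would give was not seen: in the other 4 libraries Gnas was higher in Hedgehog-responding than in basal cells, with a smallest log2 ratio of 0.113. Classes of these libraries also differ in Gnas otherwise, at 169 to 190 CPM in suprabasal and 425 to 483 in bulge cells. A comparison of classes therefore cannot exclude an effect within a cell type. An exchange of titles between the SmoM2 and Gnas-eKO libraries had the values it needs, with Gnas at a log2 fold of -2.14 against PKI in keratinocytes, its immune level within the range of the others, and the libraries labelled Gnas-eKO at -0.16 (SE 0.08, adjusted p = 0.458) against PKI. A single wrong label would give the same values for this library. Gnas should then be low in both libraries labelled Gnas-eKO too, unless their deletion left the 3' tag unchanged. It was at 362 and 367 CPM in their keratinocytes, against 420 and 401 in PKI and 93.9 in the library labelled SmoM2. If the deletion is the same in all of them, these values argue against a single wrong label. The file names give the opposite model for both groups, and the labels alone do not decide. Levels of Gt(ROSA)26Sor, a transcript of the locus where the SmoM2 allele is commonly inserted, were 22.7 CPM in the library labelled SmoM2, 12.3 and 11.2 in those labelled Gnas-eKO and 1.53 and 1.82 in PKI, a gene chosen after its values were seen. Whether an inserted allele raises or lowers this transcript was not tested, so a high level does not speak for the SmoM2 title.

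Genes called between the libraries labelled Gnas-eKO and PKI were set against a germline difference of the mouse lines, linked chromosome segments and an effect in keratinocytes alone. An effect in keratinocytes alone as the cause of every called gene is argued against: 4 of the 20 genes, Ostf1, Cwc22, Rpl29 and Prss22, exceeded in non-keratinocytes of both libraries of the higher group what free RNA allows, by exact 95% bounds and the highest marker percentage of each library. For the other 16 genes it stays open. Over the 14 genes whose mean level in non-keratinocytes was at least 50% of that in keratinocytes, the median ratio of the log2 folds was 1.03, and 12 showed at least 50% of the fold, but free RNA carries the same fold and a keratinocyte marker reached 84.1% of its keratinocyte level in Gnas-eKO 2, so a germline difference stays open too. Linked segments stay open and cannot be told apart from chance: with tandem families and overlapping genes merged, 2 of 17 loci (Glo1, and Glp1r with Gm10503) lay within 2 Mb of another, and 4195 of 10000 random sets gave at least as many. Before merging, 6 of the 20 genes lay within 2 Mb of another, above the 95th percentile of random sets (4). Tandem families and overlapping genes count as neighbours there.

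The higher tail scale and hair keratins in the library labelled SmoM2 were set against more scale and hair shaft cells, free RNA and a rise inside Hedgehog-responding cells, and these cannot be told apart. Without the 4 clusters that these genes lead the median log2 fold was 1.14, from 1.56, but removing clusters leaves their free RNA in the other cells, so a remaining fold does not go against more shaft cells. The summed list stood in immune cells at 0.905 of its level in Hedgehog-responding cells, but 147 of the 290 immune counts were of Krt2 and 59 of the 6 members that rose, 25 of them Krt71 in 1 cell. With cells thinned to 5000 UMIs, a risen member was found in 5.06% of 79 immune cells (exact 95% interval 1.40% to 12.5%) and in 10.5% of 1827 Hedgehog-responding cells (9.14% to 12.0%), and the median depths of all cells of these classes, unthinned, were 7170 and 17139 UMIs. These intervals overlap, so the rise inside Hedgehog-responding cells (median 1.13) stays open, and no other biological explanation was tested.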

How the results depend on the processing

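Fits with a sex term, with named keratinocyte clusters alone and without low-UMI clusters were added after seeing the data, and the other alternatives were fixed before. The SmoM2 group had 1 library and each other group 2. The median log2 fold of all genes stayed under 0.02 in size in each keratinocyte comparison, with TMM and with RLE scaling. Over all alternatives, named genes kept direction and side of the threshold in 1482 values, were weaker in 48, newly past it in 26 and reversed in 17. The list results were the same in 177 values and weaker in 32. Single classes and shares were the same in 121 and moved in 95. For a setting below, the cause was not tested unless it is given.

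For the libraries labelled Gnas-eKO against PKI (20 genes) the count was 688 with DESeq2, 132 with no low-count filter, 33 with libraries thinned to equal totals, 31 with no doublets removed, 36 in named clusters and 38 without low-UMI clusters. All 20 genes stayed called in each of these except named clusters, which kept 18. For the library labelled SmoM2 against the mean of the others (17), against Gnas-eKO (12) and against PKI (17), DESeq2 called 297, 326 and 387, and no filter 49, 28 and 68. The class totals (237 and 123) were 1056 and 665 with DESeq2 and 2664 and 1775 with no filter. The second was 55 with up to 20% mitochondrial counts, 76 at resolution 0.5 and 585 at resolution 2. The difference between basal and suprabasal cells (0 by edgeR, 693 at an unadjusted p under 0.05) gave 11 with DESeq2 and 16 with no filter. The difference in the share of Hedgehog-responding cells between the libraries labelled Gnas-eKO and PKI, 3.33 points, was 7.47 with up to 20% mitochondrial counts, 6.94 with no doublets removed, 6.74 and 5.36 at resolution 0.5 and 2 and 5.79 with at least 1000 genes. That of suprabasal cells, 1.15 points, changed sign in 4 of these 5, to as low as -0.96. Of 11 list results, 0 held with an estimated correlation and 2 with fry. In all cells, where other types enter, Ptgds (0.68) and Mlana (0.48) reversed between the libraries labelled Gnas-eKO and PKI.

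With a replicate block the keratinocyte counts were 101, 61, 54 and 68 and the class totals 1259 and 927, and Smo in the library labelled SmoM2 reversed to 0.010. Replicate number and sex coincide in the Gnas-eKO and PKI groups, so the sex term gave the same 101 and 1259 there. It gave 10 for the library labelled SmoM2 against the mean, 28 against PKI and 386 over classes, and reversed Sox9 (0.030) and Krt5 (0.012). The labels do not pair replicate numbers, and the differences between replicates 1 and 2 in the Gnas-eKO and PKI groups correlated across genes at r = 0.297 (0.222 on autosomes, genes are not independent).

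Leaving out each Gnas-eKO or PKI library in turn gave 4 to 8 genes between these groups, with 4 of the 20 kept each time, 0 to 4 for the library labelled SmoM2 against the mean, 2 to 4 against Gnas-eKO and 0 to 0 against PKI. The remaining library of the reduced group was assumed to vary like the others, with 1 residual degree of freedom. Class totals ranged from 198 to 1233 and from 172 to 616, the interaction from 0 to 10 and the lists from 14 to 27. In Hedgehog-responding cells the count between the libraries labelled Gnas-eKO and PKI was 137 to 952, against 136, at prior degrees of freedom of 5.84 to 13.6, against 4.31. Genes that changed sign between the libraries labelled Gnas-eKO and PKI ranged as follows: Pmel -0.27 to 0.49, Krt14 -0.16 to 0.32, Mlana -1.04 to 0.17, Smo -0.036 to 0.33, Pkia -7.0e-04 to 0.59, Gli1 -0.068 to 0.20, Sox9 -0.19 to 0.28 and Krt1 -0.20 to 0.88. In the library labelled SmoM2, Krt5 ranged from -0.12 to 0.038 and Sox9 from -0.16 to 0.079.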

Other observations

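The lists of the Hedgehog-responding class, the single clusters and the free RNA levels were chosen after the class results were seen.

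In Hedgehog-responding cells of the library labelled SmoM2, the lists of spinous layer, wounded skin and cytokine genes had positive medians and passed camera's test with the preset correlation, but none did with an estimated correlation after adjustment (0.567 to 0.575). Over all keratinocytes the spinous and wound lists had medians of -0.12 (adjusted p = 0.361) and -0.15 (adjusted p = 0.259). Spinous differentiation genes had a median log2 fold of 0.94 (camera adjusted p = 2.3e-20, and p = 0.0172 before and 0.567 after adjustment with an estimated correlation), with 1 of 13 past the threshold over all genes and 12 adjusted over the list alone. Granular and cornified envelope genes did not pass (median -0.19, with camera's direction upwards, adjusted p = 0.364, and p = 0.642 with an estimated correlation). Wound keratins and alarmins had a median of 1.35 (adjusted p = 2.6e-15, and p = 0.0189 before and 0.567 after adjustment with an estimated correlation), with 2 of 15 higher over all genes and 8 higher and 1 lower adjusted over the list alone. Chemokines and cytokines had a median of 0.61 (adjusted p = 1.8e-06, and p = 0.0303 before and 0.575 after adjustment with an estimated correlation), with 1 of 13 higher over all genes and 4 higher and 1 lower adjusted over the list alone. None of the other lists among the 12 that passed the preset test held with an estimated correlation after adjustment. The cAMP and CREB targets were lower (median -0.58, adjusted p = 0.0120, and p = 0.266 with an estimated correlation), with 0 of 17 past edgeR's threshold over all genes and 3 lower adjusted over the list alone. This was against the mean of both groups, which differed: the list was higher in the libraries labelled Gnas-eKO than in PKI (median 0.57, adjusted p = 3.2e-04, and p = 0.170 with an estimated correlation), with 2 of 17 higher over all genes and 4 adjusted over the list alone. Sik1 was at 39.8 CPM in the library labelled SmoM2, 53.5 and 41.3 in PKI and 139 and 109 in the libraries labelled Gnas-eKO.

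Clusters 1 and 3 of the class, which the libraries fill differently, were also fitted alone, without a test of the difference between them. Krt16, a keratin of wounded epidermis, was at 326 CPM in cluster 3 of the library labelled SmoM2 against 20.5 to 40.5 in the others (log2 3.46, SE 0.27, adjusted p = 0.0171, edgeR), and at 10.6 CPM in cluster 1 against 5.08 to 14.4 (0.33, adjusted p = 0.736). Tslp, an epithelial cytokine, was at 31.1 CPM in cluster 3 against 0.134 to 1.44 (adjusted p = 0.0296). Immune cells of this library, which should lack Krt16, held it at 16.4 CPM, against 109 CPM in the class. Enpp1 rose in both (4.36 in cluster 1, 4.40 in cluster 3), as did Baiap2l1 (2.09 and 1.79), while Gnas (-3.32 and -4.31) and Epas1 (-2.17 and -2.33) fell in both. Of the 79 genes changed in the class, 65 of 77 tested had the same direction in cluster 1 and 78 of 78 in cluster 3, and 48 and 76 of them kept at least 50% of the log2 fold. The class sums include the cells of these clusters, so this agreement was in part fixed in advance. Cluster 3 held 684 and cluster 1 held 371 cells of this library. Dmkn (spinous list) was at a log2 fold of 1.53 in the class, 0.18 in cluster 1 and 1.36 in cluster 3. Lgals3 was at 1.04, -0.59 and 0.69 in the same order. In the other libraries Dmkn was at 286 to 540 CPM in cluster 3 and 35.0 to 56.4 in cluster 1. A shift in cluster shares was thus not told apart from a rise within cells. Between the libraries labelled Gnas-eKO and PKI, Zdhhc14 rose in both clusters (3.59 and 4.64).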
